A study of Mus musculus with 29 samples.

How the data were processed

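The series measured polyadenylated RNA of the mouse myoblast line C2C12 after cells had been separated into a cytosol and a membrane fraction. Of the 29 samples, 26 were 3' end libraries made with 3'READS+, an assay that sequences the ends of transcripts next to the poly(A) tail, and 3 were RNA-seq libraries. Cells were either proliferating, in medium with fetal bovine serum, or differentiating, in medium with horse serum. Both fractions were run on gradients that separated polysomes from monosomes, and these 16 gradient libraries formed 8 groups of 2 replicates. Another 8 libraries came from proliferating cells left untreated or given puromycin, which releases nascent chains and so ends translation, at 100 µg/ml for 0, 30 or 60 min, with 1 cytosol and 1 membrane library each. A single cytosol and a single membrane 3' end library of whole fractions completed that assay.

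The deposited table of poly(A) sites held read counts, 1 column per 3' end library, per the file headers. Each of its 125369 entries gave a chromosome, a strand, a position and a gene symbol, and 17005 symbols occurred. The RNA-seq table held, per the file headers, deposited read counts of 11733 genes in an alternative part of the 3' UTR, between a proximal and a distal site, and in the constitutive part before it. The submitters' processing notes named genome build mm9, cutadapt, Bowtie2 and STAR 2.5.2 without saying which step used which tool. How the reads were counted, and whether the RNA-seq counting used strand, was not given in the sources used here. No genome annotation of that build was used, and gene names were taken from the files. Among the symbols of poly(A) sites, 25 had been turned into dates by a spreadsheet and were kept as they stood.

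A total of 651 positions listed under more than 1 symbol, with 0.56% of all reads, were left out, and 27739 entries had no read in any library. Reads were summed over all sites of a symbol, which gave 15954 genes with at least 1 read, and 99.9% of reads lay on the strand that held most reads of their gene. For the isoform comparisons the pair of most abundant sites of a gene on that strand, at most 10 kb apart, was ordered along the strand as proximal and distal. A pair needed a mean of at least 10 reads over both sites per library and at least 5% of those reads in the rarer site. This left 4553 genes in the gradient libraries and 4714 in the puromycin libraries, with a median of 678 nt between sites in the gradient set and a range from 25 to 10000 nt. The plan had asked for sites in the 3' UTR of the last exon, but the table marked no gene regions, so that alternative last exons and intronic sites could not be told from tandem 3' UTR sites.

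The tests, covariates, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Gene counts were filtered with filterByExpr, scaled by TMM and tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. All 16 gradient libraries entered 1 fit with a mean per group, and membrane was set against cytosol as the mean over polysome and monosome groups. The SE of a log2 fold change was taken as its size divided by the square root of F. Site pairs were tested in the same tool with the proximal and the distal count of a library as 2 columns, a term for each library and a term for isoform by group. The puromycin libraries were fitted with a term per pair, a fraction term and a fraction term per 30 min of exposure, with untreated cells coded as 0 min. A second form of the model replaced minutes by exposed (30 and 60 min) against not exposed (untreated and 0 min). The main effect of exposure had a fraction term and a term for minutes, and so took both libraries of an exposure as separate.

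A total of 23 gene lists was fixed, of which 22 had members among the genes tested. Each list was tested with camera of limma 3.58.1 at its preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison. Beside the number of members called over all genes, the number called when adjusted over the list alone is given. Named genes were the members of a list with the highest mean level or the lowest p, and up to 10 in each direction with the largest changes among genes past the threshold with a mean of at least 10 CPM and the same sign in each replicate number. For site pairs the mean had to be at least 50 reads. Symbols of clones and predicted genes were passed over.

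Per library, the median over genes of the log2 ratio of distal to proximal reads, with a pseudocount of 1 read, was compared between fractions by a two-sided exact permutation test. The relation of the site difference to the distance between sites was given as Pearson's and Spearman's correlations across genes with 100000 permutations. RNA-seq ratios were formed for genes with at least 20 reads in each region of both libraries, with a pseudocount of 1 read and intervals from counting error. List medians of these ratios were set among 10000 random lists of like read depth. Puromycin ratios per gene were formed from CPM with a pseudocount of 0.5. Intervals of shares were 95% Wilson intervals. DESeq2 1.42.0 served as another test and as another scaling. Calculations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

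The steps were tested on simulated counts with 200 changed genes drawn from the means and sizes of the real libraries, 100 at each size of change. For membrane against cytosol in proliferating cells, 84% of genes with a log2 change of 2 were recovered and 9% of those with a change of 1. Polysome against monosome in the cytosol recovered 31% at a change of 2, and differentiating against proliferating 99%. Site pairs recovered 49% at a change of 2 for membrane against cytosol in proliferating cells and 80% for the state. Unchanged genes made up between 3.6 and 12.3% of the calls, the most in the exposed against not exposed model. Simulated libraries were drawn independently, without the deviation that real libraries of a replicate number shared. These shares may therefore not hold for the real libraries, above all for the comparison of states.

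Replicates of all 8 gradient groups differed by far more than counting noise, with a chi-square per degree of freedom from 40.3 to 97.4. That excludes 1 library deposited under 2 names but not 2 libraries from 1 lysate, which the labels do not settle. Libraries with the same replicate number deviated together: across genes, the deviations from the group means correlated at 0.47 to 0.73 in all 12 pairs of groups of one state, and at 0.1 to 0.26 between states. For site ratios the ranges were 0.21 to 0.41 within and 0.14 to 0.39 between states, so for sites a number was shared by both states nearly as much as within 1. The block term of each state takes up such a shared part too, and a single block over both states was added for the comparison of states after seeing the data. In that comparison either block removes the spread between replicate numbers, so that the test rests on libraries of the same numbers alone. Pairing by number rests on the data, since the labels do not say what a number shares. The fit with the replicate number within each state as a block is printed beside a result where it changed a call or moved a count by more than 1.5 times.

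Gradient libraries held 2975406 to 8261150 reads, puromycin libraries 5519154 to 11674523, the whole fractions 5896104 and 6167559, and RNA-seq libraries 4283570 to 6521105. A floor of 3 reads amounted to 0.258 to 1.012 CPM. Intervals and floors cover counting error only, since reads made by PCR are not independent molecules. Other alternatives were DESeq2 size factors, no filter, the DESeq2 test, only the 8 libraries of a state, each library left out in turn, a mean of at least 30 reads per site pair, the outermost sites with at least 5% of reads, limma on log2 ratios, other pseudocounts and minima, and the puromycin model without the untreated pair or with the whole fractions at 0 min. Limits of 3 kb, 200 nt or none on the distance between sites, genes from sites with at least 5% of reads, leaving out the 30 or the 60 min pair, the added settings of the exposed model, both fractions of an exposure scaled to the same size and summed, and leaving out RNA-seq genes with a neighbour on the other strand were chosen after seeing the data. So were all alternatives for the relation to distance but the minimum of 30 reads, and leaving out each library for the library medians.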

Results

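Transcript 3' ends and alternative 3' UTRs were counted in cytosol and membrane fractions of C2C12 cells, a mouse myoblast line that forms muscle cells when serum is lowered. The membrane fraction holds the endoplasmic reticulum (ER), where ribosomes that make secreted and membrane proteins are bound. The gradient experiment had 16 libraries, 2 for each combination of cell state (proliferating or differentiating), fraction (cytosol or membrane) and gradient part (polysome or monosome). Membrane libraries of proliferating cells held 4887343 to 8261150 reads and their cytosol libraries 3854801 to 6102917. Differentiating cells gave 3779086 to 7364301 reads in membrane and 2975406 to 5895609 in cytosol libraries. The 8 puromycin libraries held 5519154 to 11674523 reads, and the RNA-seq libraries held 4415706 reads for cytosol, 6521105 for membrane and 4283570 for an insoluble fraction. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

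The first comparison asked which mRNAs were held in the membrane fraction of proliferating cells. Transcripts of secretory-pathway proteins were far higher in membrane than in cytosol libraries, and transcripts of ribosomal proteins were lower. Hspa5, the main chaperone of the ER lumen, stood at 636 ± 79.4 CPM (SD, n = 2) in membrane polysomes and 27.6 ± 13.9 CPM (SD, n = 2) in cytosol polysomes. Its log2 fold change over both gradient parts was 3.94 (SE 0.35, adjusted p = 3.34e-06, 4 membrane against 4 cytosol libraries). Cd63, a tetraspanin of lysosomes and the cell surface, was at 27700 ± 2750 against 714 ± 83.1 CPM (SD, n = 2) in the same groups. Rpl8, a protein of the large ribosomal subunit, was lower in membrane libraries (log2 -1.48, SE 0.28, adjusted p = 0.00123), with 9690 ± 1280 against 21100 ± 157 CPM (SD, n = 2) in polysomes.

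All 17 ER chaperones and folding enzymes tested rose in the membrane fraction, 17 adjusted over the list alone, with a median log2 change of 2.97. Their camera test gave an adjusted p of 6.38e-13, and adjusted p = 0.0542 with an estimated correlation. Pdia3, a disulfide isomerase of the ER, was higher by log2 5.05 (SE 0.28) and the chaperone Calr by 3.62 (SE 0.28). Of 21 genes of ER translocation and glycosylation, 19 rose (19 adjusted over the list alone; median 2.45, camera adjusted p = 2.67e-10, adjusted p = 0.0429 with an estimated correlation), among them Rpn1, a subunit of the oligosaccharyltransferase, by 3.13 (SE 0.25). Of 29 extracellular matrix and secreted proteins, 27 rose (27 adjusted over the list alone) with a median of 3.38 (adjusted p = 4.96e-13, and adjusted p = 0.00738 with an estimated correlation). The collagen genes Col3a1 and Col1a1 were higher by 5.20 (SE 0.39) and 3.88 (SE 0.53). Of 32 plasma membrane proteins 31 rose (31 adjusted over the list alone; median 3.25, adjusted p = 2.21e-16, adjusted p = 0.0238 with an estimated correlation), including the integrin Itgb1 by 4.02 (SE 0.30). All 15 lysosomal proteins rose (15 adjusted over the list alone; median 3.24, adjusted p = 7.78e-11, adjusted p = 0.0604 with an estimated correlation), such as the protease Ctsd by 3.37 (SE 0.39).

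Among 50 cytosolic ribosomal proteins 36 fell and 1 rose (40 and 2 adjusted over the list alone), with a median of -1.39 (camera adjusted p = 1.77e-14, adjusted p = 0.108 with an estimated correlation). Of 26 translation factors 13 fell and 2 rose (14 and 3 adjusted over the list alone; median -0.88, adjusted p = 0.000143, adjusted p = 0.163 with an estimated correlation). Many of these genes have near-identical copies elsewhere in the genome, so their counts are uncertain. All 4 nuclear-retained noncoding RNAs tested rose (4 adjusted over the list alone; median 2.06, adjusted p = 0.0285, adjusted p = 0.108 with an estimated correlation), with Neat1, the scaffold of paraspeckles, higher by 4.23 (SE 0.68) and Malat1, an RNA of nuclear speckles, by 1.70 (SE 0.40). The largest rises among genes of at least 10 CPM were in Cstf2t, which codes for a cleavage stimulation factor subunit, by 5.51 (SE 0.49), followed by Col3a1, Pdia3, Retsat (4.78), the lysosomal genes Scarb2 (4.52), Ctsl (4.52) and Grn (4.42), and the tetraspanin genes Tspan3 (4.42) and Cd81 (4.31). The largest falls were in Ccng1 (-2.14, SE 0.43), the copper chaperone gene Atox1 (-2.12), Pkig (-2.12), Sat1 (-2.11), Rpl41 (-2.10) and Hmgn1 (-2.09).

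In total, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3887 of 11176 genes, 2597 higher and 1290 lower in membrane. Pairing libraries by replicate number raised this to 6273 genes, 3754 higher and 2519 lower. The split depended on scaling: with DESeq2 size factors 2231 genes were higher and 1815 lower, and the median log2 change of all genes moved from 0.17 to 0.00 (recorded as -0.004). The lists above lay well beyond that shift.

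**Figure D1:**
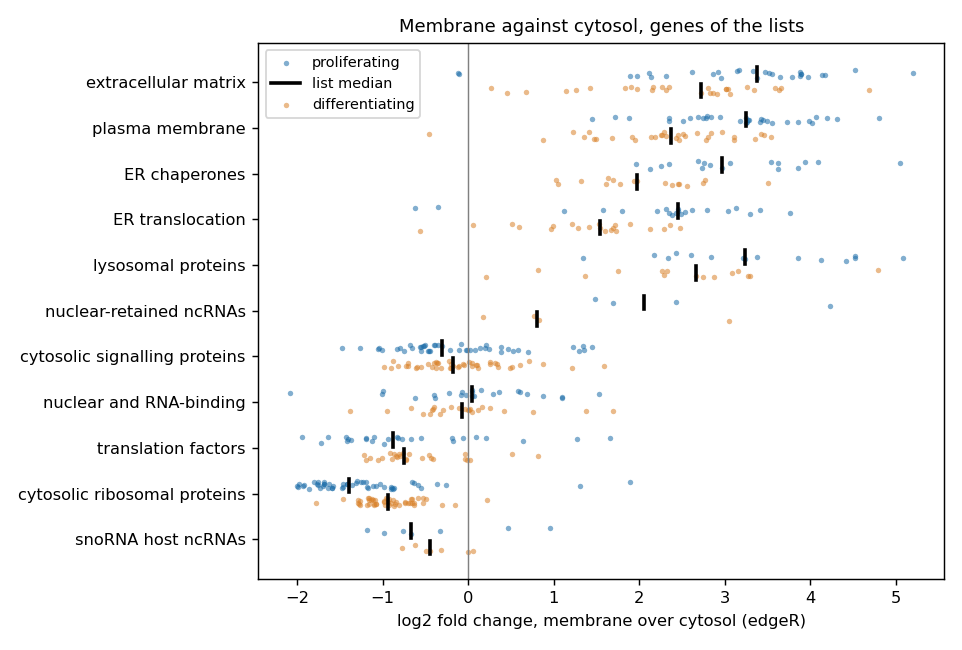
Log2 fold change of membrane over cytosol (x axis) for the genes of 11 lists (y axis) in proliferating (blue) and differentiating (orange) cells, 1 point per gene and a black bar at each list's median. Extracellular matrix genes centred on 3.38 and 2.73, ribosomal protein genes on -1.39 and -0.94.

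Differentiating cells showed the same kind of partition. The membrane fraction was enriched in Col3a1 (log2 4.69, SE 0.38), the adhesion protein gene Igsf8 (4.42), Cstf2t (4.29), the thrombomodulin gene Thbd (3.93), Cilp (3.92), Prss23 (3.85), Tmem132a (3.75), the lysosomal enzyme gene Naglu (3.70) and Col1a1 (3.66, SE 0.50). Hspa5 was higher by 2.77 (SE 0.33) and Cd63 by 2.78 (SE 0.33). Myo1h (-1.94), Gng10 (-1.63), Snrnp25 (-1.48), Ttc21b (-1.47) and Ccng1 (-1.47) fell the most, and Rpl8 fell by 0.87 (SE 0.28, adjusted p = 0.0443).

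Of 17 ER chaperones 15 rose (17 adjusted over the list alone; median 1.98, camera adjusted p = 2.33e-12, adjusted p = 0.0609 with an estimated correlation). Extracellular matrix genes rose in 25 of 29 cases (25 adjusted over the list alone; median 2.73, adjusted p = 8.99e-15, adjusted p = 0.00453 with an estimated correlation) and plasma membrane genes in 27 of 32 (30 adjusted over the list alone; median 2.37, adjusted p = 4e-17, adjusted p = 0.0208 with an estimated correlation). Lysosomal genes rose in 12 of 15 cases (14 adjusted over the list alone; median 2.66, adjusted p = 1.53e-10, adjusted p = 0.0648 with an estimated correlation) and translocation genes in 13 of 21 (16 adjusted over the list alone; median 1.55, adjusted p = 6.88e-09, adjusted p = 0.0609 with an estimated correlation). Among ribosomal protein genes 22 of 50 fell (29 adjusted over the list alone; median -0.94, adjusted p = 1.98e-13, adjusted p = 0.129 with an estimated correlation). Muscle membrane and sarcoplasmic reticulum genes were called higher in 4 of 25 cases (4 adjusted over the list alone; median 0.89, adjusted p = 0.00735, adjusted p = 0.51 with an estimated correlation). The edgeR test called 2200 genes, 1586 higher and 614 lower, and 4850 with the replicate block, 2803 higher and 2047 lower. The lower count was less stable than the higher one. DESeq2 size factors gave 1450 higher and 875 lower, and the DESeq2 test 1576 and 1155. Without cytosol polysome replicate 1 there were 1245 and 321, and without membrane polysome replicate 2 there were 1280 and 283.

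Whether membrane association changed with differentiation was tested by the interaction of state and fraction. The ratios of several lists lay nearer 0 in differentiating cells: secretory lists were less enriched and ribosomal protein genes less depleted, and no list was called with an estimated correlation. A general shrinking of the ratios was therefore not told from a change of single lists. Without pairing, 0 genes were called by edgeR, 669 had an unadjusted p under 0.05, and DESeq2 called 14. With libraries paired by replicate number 514 genes were called, 81 with a higher and 433 with a lower membrane ratio in differentiating cells. In that paired fit Hspa5 differed by -1.27 (SE 0.25, adjusted p = 0.00309; -1.17 and adjusted p = 0.738 unpaired), Pdia3 by -1.50 (SE 0.26, adjusted p = 0.000661; adjusted p = 0.683 unpaired) and Calr by -1.11 (SE 0.27, adjusted p = 0.0127; adjusted p = 0.683 unpaired). The sarcoglycan gene Sgca, part of the dystrophin complex of muscle, differed by 1.70 (SE 0.26, adjusted p = 0.000165; adjusted p = 0.716 unpaired), as did Tmem121 (1.63) and Vamp5 (1.25). Fkbp7 (-2.51), Retsat (-2.46), Ifnar2 (-2.07) and Ept1 (-1.97) had lower membrane ratios in differentiating cells.

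By list, the unpaired fit called none of the ER chaperones over all genes and 10 lower adjusted over the list alone (median -1.17, camera adjusted p = 3.58e-11, adjusted p = 0.107 with an estimated correlation). The paired fit called 12 of 17 lower (14 adjusted over the list alone; median -1.15, adjusted p = 9.17e-09, adjusted p = 0.244 with an estimated correlation). Translocation genes went from 0 (7 lower adjusted over the list alone; median -0.94, adjusted p = 3.62e-10, adjusted p = 0.107 with an estimated correlation) to 9 of 21 lower when paired, and lysosomal genes from 0 (6 lower adjusted over the list alone; median -1.05, adjusted p = 1.56e-07, adjusted p = 0.113 with an estimated correlation) to 10 of 15. Of the plasma membrane genes 0 were called unpaired, 0 also adjusted over the list alone (median -0.82, adjusted p = 3.99e-07, adjusted p = 0.113 with an estimated correlation), and 10 of 32 were lower when paired. Extracellular matrix genes went from 0 (0 also adjusted over the list alone; median -0.80, adjusted p = 0.00252, adjusted p = 0.113 with an estimated correlation) to 7 of 29 lower when paired. Ribosomal protein genes moved up, from a median of -1.39 in proliferating to -0.94 in differentiating cells, with 0 called unpaired (median difference 0.46, adjusted p = 6.19e-05, adjusted p = 0.637 with an estimated correlation).

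The next comparison asked which mRNAs lay in heavy ribosome complexes. In the cytosol of proliferating cells, transcripts of nuclear and signalling proteins were higher in polysomes, and snoRNA host transcripts and secretory-pathway transcripts were higher in monosomes. The histone chaperone gene Anp32e (log2 3.73, SE 0.34), the linker histone gene H1fx (3.73, SE 0.42), Ptms (3.21), the splicing factor gene Snrpb (3.16), Rraga (3.14), Hnrnpa0 (3.10) and Hnrnpa2b1 (3.00) were among those that rose the most. Snhg6 (-4.97, SE 0.85, adjusted p = 0.0015), Dner (-4.46), Sepw1 (-4.44), Sgcb (-4.19), Zdhhc2 (-4.01), Gdf15 (-3.90) and Atp13a1 (-3.82) fell the most.

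All 7 snoRNA host RNAs fell in cytosol polysomes (7 adjusted over the list alone; median -3.42, camera adjusted p = 5.99e-07, adjusted p = 0.0494 with an estimated correlation), among them Snhg1 by 3.42 (SE 0.48). Signalling genes rose in 20 of 45 cases (26 adjusted over the list alone; median 1.26, adjusted p = 4.19e-09, adjusted p = 0.0494 with an estimated correlation) and nuclear chromatin and RNA-binding genes in 11 of 24 (13 adjusted over the list alone; median 1.18, adjusted p = 8.88e-07, adjusted p = 0.0494 with an estimated correlation). Translocation genes fell in 13 of 21 cases (16 adjusted over the list alone; median -2.10, adjusted p = 4.19e-09, adjusted p = 0.0494 with an estimated correlation) and ER chaperones in 13 of 17 (13 adjusted over the list alone; median -1.81, adjusted p = 8.88e-07, adjusted p = 0.12 with an estimated correlation). Ribosomal protein genes fell in 24 of 50 cases (35 adjusted over the list alone; median -1.43, adjusted p = 2.63e-09, adjusted p = 0.162 with an estimated correlation). The elongation factor gene Eef2 fell by 1.99 (SE 0.44). The edgeR test called 2714 genes, 1283 higher and 1431 lower in polysomes, and 5360 with the replicate block. Leaving out cytosol polysome replicate 1 or 2 gave 1627 or 1262 genes, and leaving out cytosol monosome replicate 1 or 2 gave 1462 or 1720.

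Within the membrane fraction, snoRNA host RNAs fell in polysomes in 5 of 7 cases (7 adjusted over the list alone; median -2.85, camera adjusted p = 2.88e-16, adjusted p = 0.0165 with an estimated correlation, 7 of 7 paired). Rps28 (log2 -4.22), Rpl7 (-3.70), Snhg3 (-3.21), Ranbp6 (-2.93), Malat1 (-2.83, SE 0.54, adjusted p = 0.0359) and Snhg8 (-2.82) were among those that fell the most. Ptrf, a component of caveolae, rose by 2.13 (SE 0.34, adjusted p = 0.0165), Tgfbr2, a receptor of TGF-beta, by 2.09, the ER protein gene Txndc5 by 2.00 and Bcap31, also of the ER, by 1.85. Neat1 differed by -3.47 (SE 0.89, adjusted p = 0.0935; -3.57 and adjusted p = 6.53e-11 paired), at 30.2 ± 18.6 CPM in membrane polysomes and 336 ± 123 CPM (SD, n = 2) in membrane monosomes. ER chaperones were called higher in 1 of 17 cases (9 adjusted over the list alone; median 1.07, adjusted p = 1.72e-07, adjusted p = 0.144 with an estimated correlation) and in 14 of 17 when paired.

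For membrane polysomes against monosomes edgeR called 89 genes, 40 higher and 49 lower, with 1572 at an unadjusted p under 0.05 and 377 called by DESeq2. The paired fit called 2578, 1880 higher and 698 lower. DESeq2 size factors gave 18 higher and 73 lower and moved the median of all genes from 0.22 to 0.04. The fit of the 8 proliferating libraries alone called 0, and leaving out membrane polysome replicate 1 or 2 left 0 or 3 and membrane monosome replicate 1 or 2 left 23 or 25.

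**Figure D2:**
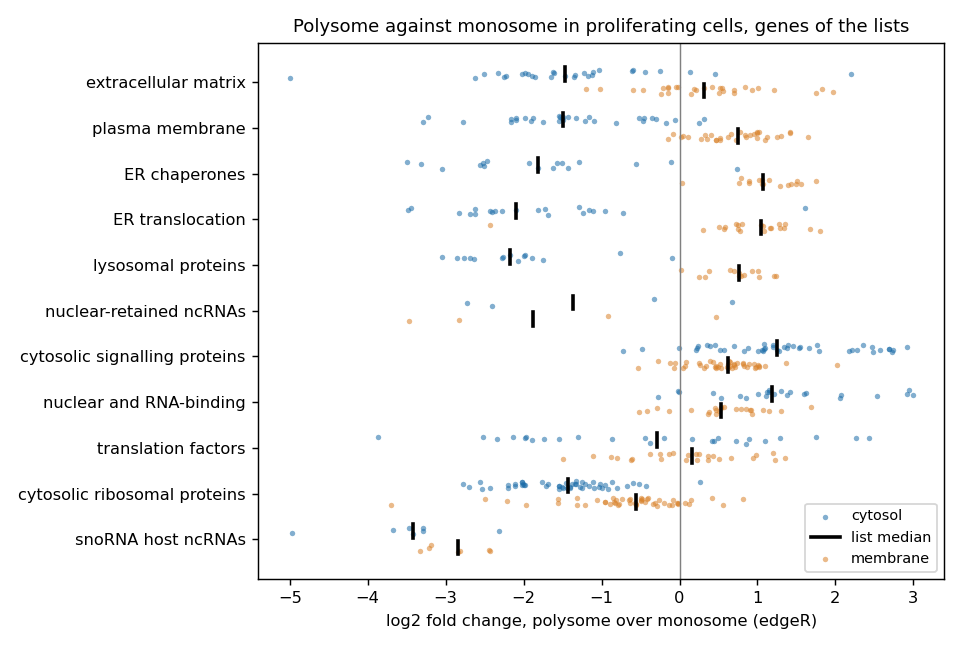
Log2 fold change of polysome over monosome (x axis) in proliferating cells for the genes of 11 lists (y axis) in the cytosol (blue) and the membrane fraction (orange), 1 point per gene and a black bar at each list's median. Medians of ER chaperones were -1.81 in cytosol and 1.07 in membrane, and snoRNA host RNAs were at -3.42 and -2.85.

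The polysome to monosome ratio differed between the fractions. Transcripts of secretory proteins had a higher ratio in the membrane fraction than in the cytosol: the difference was log2 5.36 (SE 0.51, adjusted p = 0.000352) for Sgcb, 5.11 (SE 0.48) for Rpn1, 5.03 for Fkbp7, 4.97 for Lrpap1, a chaperone of lipoprotein receptors, and 4.62 for the histocompatibility gene H2-K1. Calr differed by 2.98 (SE 0.53, adjusted p = 0.00394), Cd63 by 2.85 (SE 0.63, adjusted p = 0.0138) and Hspa5 by 1.16 (SE 0.62, adjusted p = 0.324; 1.21 and adjusted p = 0.00757 paired). Wdr5b (-3.48), Mex3a (-3.40), Rbbp7 (-3.34), Chmp1b (-3.29) and H1fx (-2.95) had a lower ratio in the membrane fraction. Translocation genes were higher in 15 of 21 cases (18 adjusted over the list alone; median 3.02, camera adjusted p = 1.51e-14, adjusted p = 0.0378 with an estimated correlation), ER chaperones in 12 of 17 (14 adjusted over the list alone; median 2.94, adjusted p = 2.13e-13, adjusted p = 0.0616 with an estimated correlation) and lysosomal genes in 11 of 15 (12 adjusted over the list alone; median 2.84, adjusted p = 1.21e-09, adjusted p = 0.0765 with an estimated correlation). The edgeR test called 815 genes, 692 higher and 123 lower. DESeq2 called 1250, 898 higher and 352 lower, and the paired fit 3180, 2018 higher and 1162 lower. Leaving out cytosol polysome replicate 1 or 2 gave 488 or 387, cytosol monosome replicate 2 gave 543, membrane polysome replicate 2 gave 397 and membrane monosome replicate 1 or 2 gave 398 or 522.

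In the paired fit the polysome to monosome ratio of many ribosomal protein genes differed between states, though their list was not called with an estimated correlation. Ribosomal protein genes had a lower ratio in differentiating cells in 32 of 50 cases there (40 adjusted over the list alone; camera adjusted p = 3.39e-33, adjusted p = 0.199 with an estimated correlation). Unpaired, 0 were called over all genes and 25 were lower adjusted over the list alone (median -1.30, adjusted p = 6.76e-40, adjusted p = 0.0565 with an estimated correlation). Rpl13 differed by -2.15 (SE 0.36, adjusted p = 0.000745 paired, 0.579 unpaired), the nucleolin gene Ncl by -1.85, Tpt1 by -1.84, the elongation factor gene Eef1b2 by -1.70 and the nucleophosmin gene Npm1 by -1.70. The apolipoprotein gene Apoe (2.30) and the troponin gene Tnnc1 (1.62) differed the other way. Over all genes edgeR called 0 unpaired, with 542 at an unadjusted p under 0.05 and 40 called by DESeq2, and 280 in the paired fit, 116 higher and 164 lower.

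Differentiating against proliferating cells, summed over fractions, checked the labels. The unpaired test took the libraries of a replicate number in a state as separate, though they deviated together (correlations of 0.47 to 0.73). The SE and adjusted p of this comparison are therefore likely too small. Muscle genes rose and cell cycle genes fell. The transcription factor gene Myog, which drives myoblast differentiation, had a mean of 294 CPM in differentiating and 1.34 CPM in proliferating libraries (log2 7.76, SE 0.74, adjusted p = 1.35e-05, 8 libraries each), and the embryonic myosin gene Myh3 236 against 0.849 CPM. Tnnc1 rose by 6.64 (SE 0.72) and the myoglobin gene Mb stood at 392 against 1.1 CPM. Ckm, muscle creatine kinase, had 2867 reads over the 8 differentiating and 9 over the 8 proliferating libraries, so its fitted fold depends on the prior count. The same holds for Dhrs7c, Pgm5, Cox8b, R3hdml and Actn2, with 3 to 7 proliferating reads each. All 27 myogenic regulators and sarcomere genes rose (27 adjusted over the list alone) with a median of 7.66 (camera adjusted p = 1.33e-23, adjusted p = 0.208 with an estimated correlation). The median was also 7.66 with Myh8, at 0 in all 8 proliferating libraries, placed at its bound of at least 56.7-fold, from a floor of 3 counts over the state. Of 25 muscle membrane and sarcoplasmic reticulum genes 22 rose and 1 fell (22 and 2 adjusted over the list alone; median 3.84, adjusted p = 1.68e-13, adjusted p = 0.208 with an estimated correlation), with Sgca up by 3.84 (SE 0.36).

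All 29 cell cycle genes fell (29 adjusted over the list alone; median -2.44, camera adjusted p = 1.72e-19, adjusted p = 0.169 with an estimated correlation), such as the cyclin gene Ccnb1 by 2.63 (SE 0.18) and the proliferation marker Mki67 by 2.19 (SE 0.33). The replication gene Mcm10 (-3.63, SE 0.18, adjusted p = 7.19e-08), Shmt1 (-3.65), Ercc6l (-3.37), Pkmyt1 (-3.21), Mybl2 (-3.19), Apln (-3.14) and the thymidine kinase gene Tk1 (-3.04) were among those that fell the most. Nuclear chromatin and RNA-binding genes fell in 13 of 24 cases (14 adjusted over the list alone; median -0.61, adjusted p = 7.07e-05, adjusted p = 0.169 with an estimated correlation). Extracellular matrix genes rose in 11 and fell in 3 of 29 cases (11 and 5 adjusted over the list alone; median 0.38, adjusted p = 0.019, adjusted p = 0.208 with an estimated correlation). The differentiating replicates were unlike: the median log2 difference of replicate 1 to replicate 2 was 2.2 over 25 genes of the myogenic and sarcomere list and -0.59 over 24 cell cycle genes. Between the proliferating replicates these differences were 0.6 and -0.55. In total 3964 genes were called by edgeR, 1818 higher and 2146 lower, and 6183 with the replicate block, 2772 higher and 3411 lower. Which direction held more genes depended on the processing: DESeq2 size factors gave 2095 higher and 1846 lower, no filter 1959 and 1848, and the DESeq2 test 2272 and 1939. It also turned without membrane polysome replicate 1 (1910 and 1803) or 2 (1709 and 1586), cytosol polysome replicate 2 (1675 and 1568) or membrane monosome replicate 1 (1952 and 1809) or 2 (1712 and 1556) of proliferating cells, and without membrane polysome replicate 2 of differentiating cells (1864 and 1843).

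The use of poly(A) sites was then compared between fractions, which was the isoform question of the study. Distal sites, which end longer 3' UTRs where both sites are in one UTR, had a larger share in membrane than in cytosol libraries. In proliferating cells the median log2 ratio of distal to proximal reads over 4553 genes was 0.475 ± 0.033 in membrane and 0.235 ± 0.034 in cytosol libraries (SD, n = 4). The membrane library was higher in 4 of 4 pairs, by 0.184 to 0.298, and the exact permutation p, two-sided, was 0.0286, the smallest that 70 splits allow. That test treats the 8 libraries as exchangeable, while those of a replicate number deviated together. An exact permutation test that swaps the fractions within pairs, chosen after seeing the data, gave p = 0.125, the smallest that 16 swaps allow, and both gradient parts of a replicate number repeated each other, with mean differences of 0.295 for replicate 1 and 0.184 for replicate 2. In differentiating cells the values were 0.574 ± 0.124 and 0.39 ± 0.148 (SD, n = 4), again higher in 4 of 4 pairs, by 0.157 to 0.21, with an exact permutation p of 0.1429 and p = 0.125 when swapped within pairs. The difference of 0.185 between these means was 0.279 when the outermost sites were used.

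**Figure D3:**
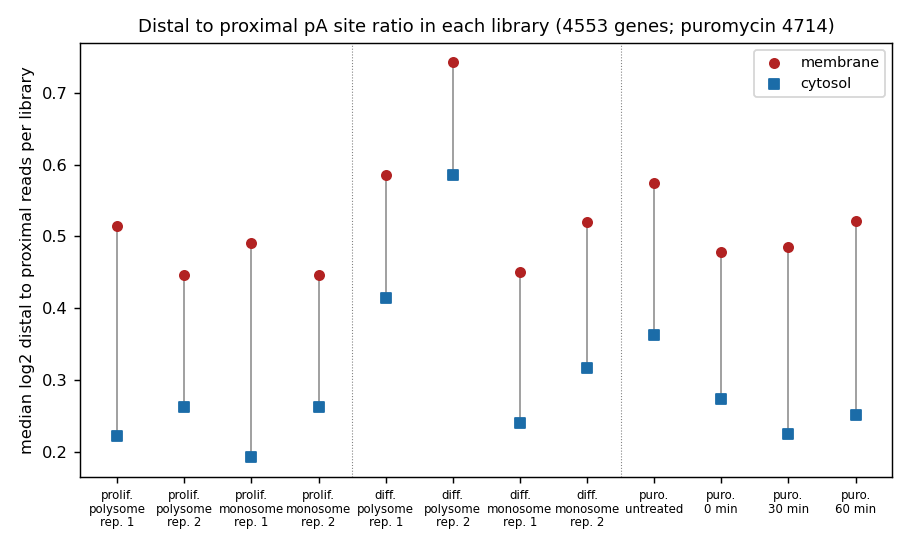
Median log2 ratio of distal to proximal reads (y axis) in each membrane (red circles) and cytosol (blue squares) library, joined within a pair, for the gradient replicates of both states and the puromycin pairs (x axis). Membrane lay above cytosol in each of the 12 pairs shown.

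Among single genes of proliferating cells edgeR called 22 of 4553 site pairs, 20 with more distal use in membrane and 2 with less. For Slc35b2, a Golgi transporter of the sulfate donor PAPS, the distal site (chromosome 17, plus strand, 45704618 in mm9, 1614 nt past the proximal site at 45703004) took 78.0 ± 9.2% of reads in membrane polysomes and 30.6 ± 5.8% in cytosol polysomes (SD, n = 2), a log2 change of 2.46 (SE 0.36, adjusted p = 0.00295). In differentiating cells the shares were 85.2 ± 4.8% and 47.3 ± 6.7% (SD, n = 2; log2 2.22, adjusted p = 0.0307), the single pair called there. Limma called a different pair instead, with less distal use in membrane. Vapb, an ER protein that tethers other membranes, changed by 2.81 (SE 0.43, adjusted p = 0.00295) between sites 6015 nt apart, and the kinase gene Stk35 by 2.49 (SE 0.40, adjusted p = 0.0042) between sites 4299 nt apart. Lsm11 (2.54), Asb1 (2.46), Myadm (2.29), Fem1a (2.15), the deubiquitinase gene Bap1 (2.04), Fam111a (2.04) and the heterochromatin protein gene Cbx5 (2.01) followed. Rpl27a had less distal use in membrane (-1.35, SE 0.24, adjusted p = 0.0104).

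With pairing, 284 site pairs were called in proliferating cells, 232 with more distal use in membrane and 52 with less, and 76 in differentiating cells, 70 and 6. Unpaired, 413 and 271 pairs had an unadjusted p under 0.05. Leaving out 1 library in proliferating cells gave 6 and 11 pairs without cytosol polysome replicates 1 and 2, 6 and 13 without cytosol monosome replicates 1 and 2, 11 without membrane polysome replicate 2, and 9 and 10 without membrane monosome replicates 1 and 2. In differentiating cells leaving out any library but membrane polysome replicate 2 left 0 pairs, which were cytosol polysome replicates 1 and 2, cytosol monosome replicates 1 and 2, membrane monosome replicates 1 and 2, and membrane polysome replicate 1. A limit of 3 kb between sites left 9 pairs in proliferating cells and no limit gave 57, while no limit gave 9 in differentiating cells and a minimum of 30 reads gave 0.

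The difference between fractions grew with the distance between sites. In proliferating cells the median log2 change was 0.00 for 1176 genes with sites up to 200 nt apart, 0.14 for 756 genes at 500 to 1000 nt, 0.46 for 613 genes at 2000 to 4000 nt and 0.56 for 343 genes at 4000 to 10000 nt. Across the 4553 genes Spearman's rho was 0.201 and Pearson's r 0.173, and 0.15 and 0.115 in differentiating cells (permutation p = 1e-05 for each, the smallest that 100000 permutations give). The rho of differentiating cells fell to 0.081 without cytosol monosome replicate 1, a check chosen after seeing the data. Genes are not independent replicates, and 3 such relations were computed from fitted changes, beside those of the single puromycin pairs. Changes between states in the membrane effect on single pairs were not called (0 by edgeR, 142 at an unadjusted p under 0.05, 0 by limma), and 5 with pairing, among them Usp36 (1.62), Rpl27a (0.97), Fem1a (-1.57) and Cbx5 (-1.44).

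**Figure D4:**
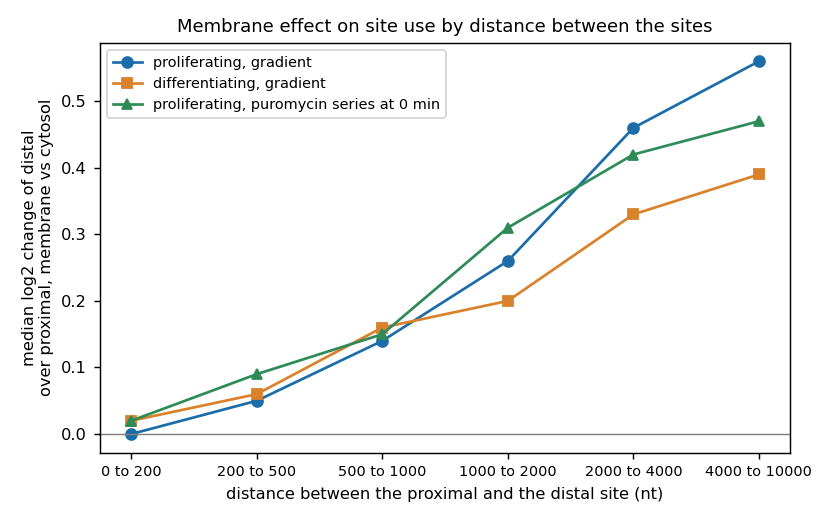
Median log2 change of distal over proximal site use in membrane against cytosol (y axis) for genes grouped by the distance between both sites in nt (x axis), for proliferating and differentiating gradient libraries and the puromycin series at 0 min. All 3 lines rise from 0.02 or less to 0.39 or more.

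Site use also differed between polysomes and monosomes and between states. In proliferating cells edgeR called 15 pairs for polysome against monosome, 7 more and 8 less distal in polysomes, and 98 with pairing. The distal share of Bap1 was 90.5 ± 0.6% in cytosol polysomes and 53.0 ± 12.0% in cytosol monosomes (SD, n = 2; log2 2.40), and that of Btg2, an antiproliferative gene, was 59.5 ± 13.4% and 89.7 ± 12.0% (SD, n = 2; log2 -2.94). Osgep (4.51), Pcbd2 (3.59) and Gemin4 (3.04) were more distal in polysomes, and Klhl7 (-3.93), Slx1b (-2.49) and Rnaseh2c (-2.37) less. Leaving out cytosol polysome replicate 1 or 2 gave 7 each, membrane polysome replicate 1 gave 4, cytosol monosome replicate 1 gave 8 and membrane monosome replicate 2 gave 7, a 3 kb limit gave 3, no limit 35 and limma 8.

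Between states 68 pairs were called, 49 more and 19 less distal in differentiating cells, by a test that took libraries of a replicate number as separate. With the replicate number as a block within each state 455 were called, 326 more and 129 less distal. With 1 block over both states, chosen after seeing the data, 378 were called. Both blocks take the spread between replicate numbers out of the test, so these counts do not speak for other samples. A split of the 16 libraries by replicate number instead of state, also made after seeing the data, called 611 pairs against 59 in the same unpaired model. The tropomyosin gene Tpm2 shifted to its proximal site (log2 -5.52, SE 0.56, adjusted p = 0.00118; chromosome 4, minus strand, 43528554 and 43527583 in mm9), with a distal share of 98.0 ± 0.3% in proliferating and 49.1 ± 26.2% in differentiating cytosol polysomes (SD, n = 2). Tpm3 changed by -4.67 (SE 0.75), and Pdlim7, a protein of the actin cytoskeleton, by -2.17 (SE 0.18, adjusted p = 6.35e-07), from 43.2 ± 7.3% to 16.7 ± 3.3% (SD, n = 2) in the same groups. Gsk3b, a kinase of Wnt and insulin signalling, shifted to its distal site (4.22, SE 0.46, adjusted p = 2.09e-05), from 4.6 ± 1.1% to 32.3 ± 11.7% (SD, n = 2). Rptor, the mTOR partner (4.16), Nufip2 (2.35) and the prion protein gene Prnp (2.17) shifted the same way. Tropomyosin genes have alternative last exons, which these tables do not tell from tandem sites. The spread of Tpm2 in differentiating cells came with the myogenic and sarcomere list, at a median log2 of 2.2 higher in replicate 1. Leaving out 1 proliferating library gave 39 without cytosol polysome replicate 1, 38 without its replicate 2, 44 without membrane polysome replicate 1, 40 without cytosol monosome replicate 2 and 37 without membrane monosome replicate 2, and limits of 3 kb or none gave 19 or 133.

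The RNA-seq libraries gave another measure of the isoforms, with 1 library per fraction and so no replicate check and no p for the difference between fractions. The ratio of alternative to constitutive 3' UTR reads was higher in membrane than in cytosol for 2646 of 3349 genes (79.0%), with a median log2 difference of 0.468 and quartiles of 0.10 and 0.84. The counting interval lay above 0 for 1638 genes and below 0 for 234. Among genes with at least 50 reads in each region the largest values were those of Nelfcd (5.15), the kinase gene Cdk4 (4.17), Brd7 (3.94), the mitochondrial channel gene Vdac3 (3.77) and Ddx39 (3.66), and the lowest those of Aebp1 (-5.49), Ctsz (-5.49), Slc35b2 (-4.57), Cd63 (-4.33) and Tspan31 (-4.21). Slc35b2 thus had opposite signs in the 2 assays, and a site of Hsp90ab1 on the other strand lay in or near its span. Matrix and plasma membrane lists lay lowest: the median of 15 extracellular matrix genes was -0.35 (percentile 0.0 among 10000 random lists of like read depth) and that of 9 plasma membrane genes -0.17 (percentile 0.4), against 0.68 for 31 signalling genes (percentile 94.6). Lists outside the secretory pathway also lay low, with 0.24 for ribosomal proteins (percentile 2.2), 0.25 for translation factors (percentile 4.4) and 0.32 for nuclear chromatin and RNA-binding proteins (percentile 7.8). Across 571 genes with an other-strand neighbour within 2 kb, values rose with its membrane change minus the gene's own (Spearman's rho 0.39, permutation p = 0.0001). Reads of such neighbours would lower the values of membrane-enriched genes. List medians were not recomputed without these genes, so an isoform difference of the matrix and plasma membrane lists was not told from such reads. Across 1733 genes no relation of the values to the 3' end site changes in proliferating cells was detected (Spearman's rho 0.042, permutation p = 0.08; Pearson's r 0.029, permutation p = 0.2, 57.1% of the same sign; 1 of 8 such relations). Both measures were mostly above 0, which alone raises the share of the same sign. With at least 100 reads per library rho was 0.095 (permutation p = 0.002, 1028 genes), and for the insoluble library it was 0.09 (permutation p = 0.0004) over all genes and 0.139 (permutation p = 0.0001) at that depth. The site changes of the puromycin series before exposure showed no such relation to the membrane library (rho 0.02, permutation p = 0.4; r -0.022, permutation p = 0.3; 1756 genes), nor with at least 100 reads (rho 0.054, permutation p = 0.07; r -0.01, permutation p = 0.7; 1166 genes). For the insoluble library rho was 0.074 (permutation p = 0.003) and 0.108 (permutation p = 0.0004) at that depth, while r was -0.006 and -0.009.

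The single whole-fraction pair, also without a replicate check, gave like gene ratios. Across 7690 genes its membrane to cytosol log2 ratio correlated with the gradient comparison at r = 0.899 and rho = 0.846, with 81.8% of the same sign (permutation p = 0.0001, the smallest that 10000 permutations give, across genes that are not independent replicates). The medians of 15 ER chaperones, 18 extracellular matrix genes and 38 ribosomal protein genes were 4.42, 3.93 and -1.19.

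The puromycin series asked whether membrane association needs translation. After 30 and 60 min the membrane enrichment of secretory-pathway transcripts was gone or much smaller. The log2 membrane to cytosol ratio of Hspa5 was 4.22 in untreated cells, 4.73 at 0 min, -0.07 at 30 min and -0.38 at 60 min. For Cd63 the values were 4.17, 4.67, -0.28 and -0.24, for Sod3, a secreted superoxide dismutase, 5.53, 6.22, -0.02 and -0.26, and for Spp1, a secreted phosphoprotein, 4.19, 4.63, -1.76 and -1.77. Col1a1 kept ratios of 3.35 and 3.61 at 30 and 60 min, after 3.70 and 4.58, and Neat1 had 4.90 and 5.63 after 2.84 and 3.88. Rpl8 went from -1.70 and -1.51 to -0.17 and 0.00.

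The 17 ER chaperones had median ratios of 3.93 and 4.64 before and -0.39 and -0.38 after exposure. All 17 were lower in both exposed pairs than in both others. The exposed against not exposed model took both exposed pairs as replicates of each other, and both other pairs likewise. Its SE and p-values therefore measure how alike different exposures were, not the spread of replicate exposures. In the exposed against not exposed model all 17 fell (17 adjusted over the list alone; median change -4.52, camera adjusted p = 5.68e-13, adjusted p = 0.203 with an estimated correlation). Lysosomal genes fell in 14 of 15 cases (14 adjusted over the list alone; median -4.83, adjusted p = 6.61e-12, adjusted p = 0.146 with an estimated correlation) and plasma membrane genes in 27 of 32 (27 adjusted over the list alone; median -3.43, adjusted p = 7.23e-15, adjusted p = 0.146 with an estimated correlation). Extracellular matrix genes fell in 20 and rose in 1 of 28 cases (21 and 1 adjusted over the list alone; median -2.60, adjusted p = 9.17e-09, adjusted p = 0.424 with an estimated correlation), and their median ratios stayed at 1.24 and 0.71 in the exposed pairs. Ribosomal protein genes rose in 39 of 51 cases (41 adjusted over the list alone; median 1.26, adjusted p = 1.23e-11, adjusted p = 0.19 with an estimated correlation). The largest falls were in Sod3 (-6.83, SE 0.38), Spp1 (-6.18), Tspan6 (-5.86), the basigin gene Bsg (-5.83), Aplp1 (-5.77) and the tetraspanin gene Cd9 (-5.55), and the largest rises in Zfp316 (2.98), Ppp1r12c (2.83), the polarity gene Scrib (2.80), Rps6ka4 (2.65) and Sbf1 (2.58).

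**Figure D5:**
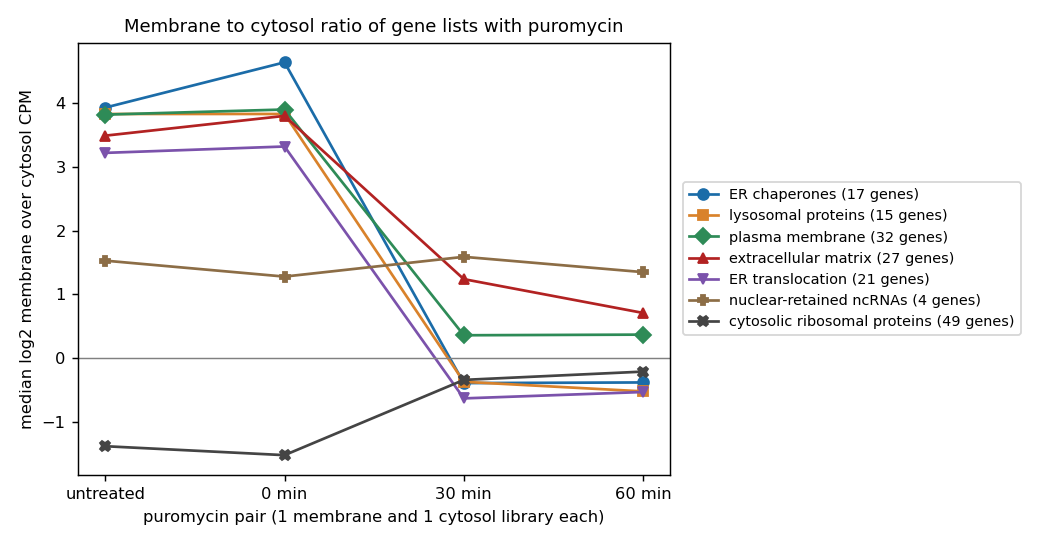
Median log2 ratio of membrane to cytosol CPM (y axis) of 7 gene lists in the untreated, 0, 30 and 60 min puromycin pairs (x axis), 1 line per list and 1 library per fraction and point. ER chaperones went from 3.93 and 4.64 to -0.39 and -0.38, and ribosomal protein genes from -1.38 and -1.52 to -0.34 and -0.21.

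The main puromycin model, linear in minutes, called 0 genes by edgeR for minutes by fraction, with 2610 at an unadjusted p under 0.05. Ratios at 30 and 60 min were alike (r = 0.91 across 7635 genes), with ER chaperone medians of -0.39 and -0.38. A line in minutes describes such a step poorly, so the 0 calls do not show that ratios stayed the same. Exposed against not exposed called 3960, 1879 with a higher and 2081 with a lower membrane ratio after exposure. Those calls rest on different exposures taken as replicates. No other tool was run on the linear model. With the whole fractions added at 0 min the linear model called 1163, and without the 30 or the 60 min pair 2637 or 2615. Before exposure, 4758 of 10465 genes differed between fractions, 2616 higher and 2142 lower in membrane, among them Sod3 (5.42), Tmem132a (5.41), Calm2 (-2.78) and the ferritin gene Fth1 (-2.37), but 0 without the untreated pair. The exposed against not exposed model called 6410 genes for the same difference, and 5846 without the untreated pair. For the lists the linear model called 0 members over all genes and, adjusted over the list alone, 17 ER chaperones lower (camera adjusted p = 2.66e-10, adjusted p = 0.531 with an estimated correlation) and 25 ribosomal protein genes higher (adjusted p = 1.87e-11, adjusted p = 0.531 with an estimated correlation).

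Abundance with exposure time, both fractions together, rose for immediate early genes. The test counted the cytosol and the membrane library of a time point as separate although they share an exposure, so its p-values rest on 4 exposures without replicates. The edgeR test called 54 genes, 53 up and 1 down per 30 min, among them the histone genes Hist3h2a (1.60, SE 0.20, adjusted p = 0.0197), and Hist1h1c (1.40), the phosphatase gene Dusp1 (1.39, SE 0.14, adjusted p = 0.0145), Klf2 (1.28), Klf10 (1.22), the AP-1 gene Jun (1.19, SE 0.11, adjusted p = 0.0145), Btg2 (1.19) and Nfkbia (1.12), and Ccnf (-1.15), a cyclin. Of 23 immediate early genes 10 rose (21 adjusted over the list alone; median 1.05, camera adjusted p = 1.1e-26, adjusted p = 0.0165 with an estimated correlation). The count was 1 without the untreated pair, 27 with the whole fractions, 0 without the 30 min pair, 0 without the 60 min pair and 9 in the exposed against not exposed model, where 4 immediate early genes rose (18 adjusted over the list alone; adjusted p = 3.2e-22, adjusted p = 0.28 with an estimated correlation).

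Distal sites stayed higher in the membrane fraction after puromycin. Over 4714 genes the median difference between membrane and cytosol in the log2 ratio of distal to proximal reads was 0.173 in untreated cells, 0.17 at 0 min, 0.239 at 30 min and 0.272 at 60 min, and 57.9, 57.1, 61.9 and 63.4% of genes were higher in membrane. Before exposure edgeR called 121 pairs, 96 more and 25 less distal in membrane, among them Slc35b2 (2.60, SE 0.31, adjusted p = 1.21e-06), the amino acid transporter gene Slc38a2 (2.74), Epha1 (3.52) and Whsc1 (2.89) upward and Rps12 (-5.43, SE 0.46) downward. The count was 189 without the untreated pair, 11 with the whole fractions, 45 and 29 without the 30 and the 60 min pair, 72 with a 3 kb limit and 218 with none. The change of the fraction effect with minutes was called for 1 pair, Prnp (-2.95, SE 0.52, adjusted p = 0.0164), with 262 at an unadjusted p under 0.05, and for 9 pairs in the exposed model. The count was 9 without the untreated pair, 0 with the whole fractions, 0 with a minimum of 30 reads, 0 with a 3 kb limit and 7 with none. The distal share of Prnp in the cytosol went from 40.0% (95% Wilson interval 23.4 to 59.3%) in untreated cells and 33.3% (19.8 to 50.4%) at 0 min to 89.4% (84.1 to 93.1%) at 30 min and 91.2% (84.5 to 95.1%) at 60 min, and in membrane from 86.1% (82.8 to 88.8%) and 78.3% (72.3 to 83.3%) to 62.4% (55.5 to 68.9%) and 68.3% (62.2 to 73.8%). The relation to the distance between sites before exposure had rho = 0.187 and r = 0.132 (permutation p = 1e-05, the smallest that 100000 permutations give).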

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

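Of the tests in this part, those of nuclear RNA in the membrane fraction, of mixing and scaling in the puromycin series, and of other splits of the libraries were chosen only after the results were seen. Some results went beyond the comparisons of 2 groups. The polysome to monosome ratio of 815 genes differed between the membrane and the cytosol of proliferating cells, so that ratio cannot be given as 1 value per gene. With libraries paired by replicate number, the membrane ratio of 514 genes and the polysome ratio of 280 genes differed between states, as did the membrane effect on 5 site pairs. The unpaired main fit called 0 in each of these comparisons. In the exposed against not exposed model the membrane ratio of 3960 genes and of 9 site pairs differed after puromycin. That model took different exposures as replicates, so its calls do not rest on replicate exposures. The main model, linear in minutes, called 0 genes and 1 pair. The insoluble RNA-seq library, which no main comparison used, had a median log2 ratio of alternative to constitutive UTR reads of 0.455 over the cytosol library, near the 0.468 of the membrane library.

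The higher distal use in membrane could come from nuclear RNA, in which long isoforms may be common. Malat1 and Neat1 together stood at 33.1 CPM in membrane polysomes, 9.3% of the 357 CPM in membrane monosomes. Yet the site difference in polysomes was 0.987 times that in monosomes. Nuclear RNA that sediments as these noncoding RNAs do was thus not the main source in the gradient libraries. Whether nuclear mRNA follows them in the gradient was not measured, so it was not excluded. The puromycin and RNA-seq libraries were not tested for this source, and Neat1's membrane ratio rose after exposure. Deeper membrane libraries were excluded, as thinning all 8 libraries to the smallest left 1.021 times the difference. The relation to the distance between sites held after puromycin: the smaller of the 2 exposed correlations was 0.225, against 0.16 in untreated cells and 0.14 at 0 min. Each value came from 1 library per fraction across genes that are not replicates, and no sample measured whether translation had stopped.

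The loss of membrane enrichment after puromycin could come from mixing of both fractions. Mixing would also bring the site difference to 0, but the smaller of the exposed values was 0.239, which excludes full mixing. Scaling would move all lists the same way, and the ribosomal protein list rose by 1.04 while the secretory lists fell, so scaling alone was excluded. With 1 library per fraction and time point, a partial loss of separation was not tested.

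The most extreme RNA-seq values could come from reads of another gene. Of the named genes with known sites, 72.2% (13 of 18) had a site of an other-strand gene in or within 2 kb of their span, against 19.9% (618 of 3105) of the rest (odds ratio 10.5, Fisher exact p = 2.6e-06, two-sided). This source fits many of the extremes, mostly negative ones. For Cdk4 (4.17), Brd7 (3.94), Vdac3 (3.77), Fdft1 (3.51) and Tspan31 (-4.21) no such site was found, and these stay open. Their own membrane log2 changes were -1.09, -0.76, -0.48, 0.43 and 1.2 in that order. All but that of Fdft1 were opposite in sign to the RNA-seq value, as neighbour reads would tend to give. The search saw only counted poly(A) sites within 2 kb, so it does not exclude a neighbour for these genes. Nelfcd (5.15) and Dnaaf2 (3.6) had no known sites under those symbols and were not searched. Nor was the relation limited to the extremes, with rho = 0.39 across the 571 genes given above. The median over genes for which no such site was found was 0.51. Whether the counting kept strands apart is not given in the sources used here. Libraries of the same replicate number deviated together, and whether the differentiating replicates differed in the extent of differentiation stayed open by the correlation test. The correlation of their difference with the state change was 0.367, but that of the proliferating replicates was 0.344. The myogenic and sarcomere list was higher in replicate 1 by a median log2 of 2.2 in differentiating and 0.6 in proliferating cells. Cell cycle genes were lower there by like amounts in both states (-0.59 and -0.55).

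Other splits of the same libraries were counted to see whether chance could be excluded. With all libraries taken as exchangeable it could for membrane against cytosol genes in proliferating cells (2116 genes, 1 for the highest other split, 1 of 35 splits as large), and at 0 min of puromycin for genes (4758 and 2564, 1 of 35) and site pairs (121 and 61, 1 of 35). On the same terms it could for the state genes, with 1291 against 1732 in a split mostly of cytosol from membrane (2 of 100 splits as large), and for the state site pairs, with 59 against 117 in a split mostly of replicate numbers (2 of 100). Libraries of a replicate number deviated together, however, and those of an exposure were paired by design. Splits that part every pair number 8, and splits of both states that keep the libraries of a replicate number together number 3, which is too few for a share under 0.05. The highest other count among them was 0 for proliferating membrane genes, 2564 genes and 61 site pairs at 0 min, and 43 for the state genes. For the state site pairs the split of replicate 1 from replicate 2 called 611 against 59, so structure between replicate numbers outdid the states. The 455 pairs called with the number as a block do not answer this, as the block takes that spread out of the test.

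By the share of splits alone it was not excluded in 4 other cases, where the larger splits followed known structure of the samples. For differentiating membrane genes (310, 2 of 35) the larger split was that of polysomes from monosomes (604), splits along no named factor called 0, and the paired fit called 4850.

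For site pairs the split by replicate number, which pairs the libraries, gave the most. Proliferating membrane had 25 against 255 (2 of 35 splits as large), with 5 for the split of polysomes from monosomes and at most 1 along no named factor, and the paired fit called 284. Polysomes had 5 against 255 (3 of 35, the others being the replicate and the membrane split), at most 1 along no named factor, and 98 when paired. Differentiating membrane had 0 against 222 (35 of 35), so this unpaired count shows nothing, and 76 when paired.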

How the results depend on the processing

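Counts stayed within a factor of 1.5 in 174 alternatives and moved further in 95, and 64 of 68 other values kept their direction and either their call or their place within the spread. The 174 include alternatives where both counts were 0, as in most for the state differences in membrane and polysome ratio. Those say little about stability. Direction was not always kept: more genes rose than fell between states with DESeq2 size factors (2095 and 1846), no filter (1959 and 1848), the DESeq2 test (2272 and 1939) and 6 of the libraries left out, against 1818 and 2146. The single differentiating membrane pair was replaced in limma by another of the other direction, polysome site pairs (7 more and 8 less distal) had more increases than decreases in most alternatives, membrane polysome genes (40 and 49) had so when paired, and the 1 pair for puromycin minutes by fraction, a decrease, gave way to 6 increases and 3 decreases in the exposed model. The length correlation of differentiating cells went from 0.15 to 0.081 without cytosol monosome replicate 1, and their median site difference from 0.185 to 0.279 with the outermost sites. Of 3686 checks on named genes 3148 gave the same call, 469 a weaker, 69 a stronger and 0 a reversed one. The cause was not tested. Pairing libraries by replicate number (a replicate block) raised most counts: to 6273 (from 3887) and 4850 (from 2200) genes for membrane against cytosol in proliferating and differentiating cells, 514 (from 0) for their difference, 5360 (from 2714) and 2578 (from 89) for polysomes in cytosol and membrane, 3180 (from 815) for the difference between fractions, 280 (from 0) for that between states and 6183 (from 3964) for states. Site pairs went to 284 (from 22), 76 (from 1), 5 (from 0), 98 (from 15) and 455 (from 68) for membrane in proliferating and differentiating cells, their difference, polysomes and states. One block over both states, chosen late, gave 378 pairs for states, and its 5211 genes were within the factor. Among named genes the replicate block made 0 calls weaker and 16 stronger of 202, and changed no other call. The DESeq2 Wald test called 14 and 40 genes for the state differences in membrane and polysome ratio, 377 for membrane polysomes and 1250 for the difference between fractions. The 8 libraries of proliferating cells alone gave 0 for membrane polysomes. Limma gave 3 pairs for proliferating membrane and 8 for polysomes. Sites at most 3 kb apart gave 9, 3, 19 and 72 pairs for proliferating membrane, polysomes, states and 0 min of puromycin and 0 for minutes by fraction. No limit gave 57, 35, 133, 218 and 7 for the same results and 9 for differentiating membrane. At least 30 reads gave 0 for differentiating membrane and 0 for minutes by fraction. Leaving out 1 library gave, lowest to highest, 1262 to 1720 genes for cytosol polysomes, 0 to 25 for membrane polysomes and 387 to 623 for the difference between fractions. For site pairs it gave 6 to 16 (proliferating membrane), 0 to 1 (differentiating membrane), 4 to 13 (polysomes) and 37 to 62 (states), and it left the gene counts of proliferating membrane at 3029 to 3498, differentiating membrane at 1563 to 1830 and states at 3243 to 3944. In the puromycin series, minutes by fraction went from 0 genes to 1163 with the whole pair, 3960 for exposed against not exposed, 2637 and 2615 without the 30 or 60 min pair, and for the exposed model 3747 without the untreated pair, 3000 with the whole pair and 3874 with DESeq2 size factors. Minutes alone went from 54 to 1 without the untreated pair, 27 with the whole pair, 9 for exposed against not exposed, 0 without the 30 min and 0 without the 60 min pair, and for the exposed model 0 without the untreated pair, 3 with the whole pair and 2 with DESeq2 size factors, and 60 with both fractions of an exposure summed, a late choice. Membrane genes at 0 min went from 4758 to 0 without the untreated pair. Its site pairs went from 121 to 189 without the untreated pair, 11 with the whole pair, 45 without the 30 min and 29 without the 60 min pair, and pairs for minutes by fraction from 1 to 9 without the untreated pair, 0 with the whole pair and 9 for exposed against not exposed. An estimated correlation left 13 of 111 list calls. The RNA-seq median went from 0.468 to 0.51 and the share of genes higher from 79.0 to 81.9% without genes found to have an other-strand neighbour, and to 82.7% with at least 50 reads. An alternative restricted to sites in the last exon was not run, as the tables annotate no regions. In simulated data the weakest power was that for cytosol polysomes, and the smallest library held 2975406 reads, so counts of 0 do not exclude small changes.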

Other observations

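The tests of puromycin mixing and scaling and of nuclear RNA cited here were chosen only after the results were seen. Membrane ratios after puromycin differed among secretory transcripts, although no test compared the lists. ER chaperones went from medians of 3.93 and 4.64 to -0.39 and -0.38 at 30 and 60 min. Extracellular matrix genes went from 3.49 and 3.8 to 1.24 and 0.71, with 22 of 27 lower in both exposed pairs, while Col1a1 went from 3.70 and 4.58 to 3.35 and 3.61. Neat1 rose to 4.90 and 5.63, and the nuclear-retained RNAs as a list stayed at 1.59 and 1.35. Distal sites kept their membrane difference, at 0.239 and 0.272 in the exposed pairs.

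A hypothesis is that a part of the membrane association is carried by the sequence between both sites and does not need ribosomes. It goes with the exposed length correlation of at least 0.225, and with medians of 0.67 and 0.76 for sites 2000 to 10000 nt apart at 30 and 60 min, against 0.42 and 0.44 in untreated cells and at 0 min. More nuclear RNA in the exposed membrane libraries would be a rival source and was not tested. Neat1's ratio rose over the same pairs, while the nuclear-retained list changed little. The insoluble RNA-seq library also had a median of 0.455 over cytosol, near the 0.468 of the membrane library. Reporter mRNAs with the Slc35b2 or Stk35 distal stretch behind a cytosolic coding sequence, fractionated with and without puromycin, would test the hypothesis. A second hypothesis is that some matrix transcripts such as Col1a1 are held by large complexes that sediment with membranes, which a detergent extraction of the exposed membrane pellet would test. The site difference of 0.239 excludes full mixing, but replicate exposures would be needed for both.

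A further hypothesis is that ER chaperone transcripts leave the membrane in differentiating cells because their translation falls. A general shrinking of all ratios is not excluded, since the ribosomal list moved toward 0 as well. The paired count of 514 genes is in line with either. Unpaired, 0 genes were called by edgeR (669 at an unadjusted p under 0.05, 14 by DESeq2). The median of the ER chaperones was -1.17 there and -1.15 when paired. In this balanced design the block leaves fold changes nearly as they were, so the likeness of both medians decides nothing. Ribosome profiling of both fractions with 3 or more separate cultures per state would decide. A last hypothesis, not tested here, is that the rise of immediate early genes with puromycin reflects stabilised transcripts. As 0 genes were called without the 30 min or without the 60 min pair, where fewer libraries alone can remove calls, more time points come first.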
